A study of Mus musculus with 28 samples.

How the data were processed

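RNA came from left brain hemispheres of C57BL/6 mice that were kept in RNAlater and frozen, and was extracted with a modified Qiagen column kit, per the labels' protocols. A sequencing company prepared the libraries by selecting polyadenylated RNA, per the same protocols. Reads were trimmed with Trim Galore 0.6.10 and assigned to transcripts with kallisto 0.50.1 on build GRCm39, per the submitters' processing notes. Neither the release of the transcript set nor the strandedness of the libraries is stated in the sources used here, so overlapping and antisense genes cannot be told apart. The authors deposited 2 tables per mouse, each with estimated counts for 126126 transcripts, and the first also with TPM values that kallisto scaled to each library, per the file headers. The second table holds the same estimated counts with fewer digits rounded off, since 159 of 917840 gene values differed after rounding to whole numbers.

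Estimated counts of the first table were summed per gene and rounded to whole numbers. The files give transcript identifiers without gene names, and the reference at hand was a mouse annotation of the earlier build GRCm38. It was used to assign transcripts to named genes and for GC content, and no coordinates are given. Transcript lengths were those given with the deposited counts. It held 93.55% of the transcript identifiers, which carried 98.93% to 99.17% of the counts and formed 32780 genes, and the other 8134 transcripts were left out. The total estimated count per library was 17.09 to 31.95 M, where M is the unit of CPM and TPM. Mitochondrial genes took 2.32% to 8.34% of the counts. The spread between mice, with 4 per group, limits the precision, and for genes near 0 CPM such as Chtf8 and Plaur counting error adds to it.

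Groups were taken from the sample labels, and S and SD were read as vehicle controls because the design names 4 metabolites and vehicles. Genes were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test with robust dispersion, TMM factors and the filterByExpr filter by group, and p was adjusted by Benjamini-Hochberg within each comparison, with calls at an adjusted p under 0.05. Every adjusted p of a gene in the text is from this test unless another tool is named. Expt1 was fitted on its 8 libraries, and the comparisons of Expt2 on all 20 of its libraries, so that its 5 groups shared 1 estimate of the spread. GDCA, IAA and PA were each compared with S and with SD on equal terms, SD with S, and the 5 groups in 1 joint test. The S groups of the 2 experiments were compared in a fit of all 28 libraries. The median log2 change over all tested genes was within 0.005 of 0 in each comparison. CPM values use the TMM-scaled library sizes.

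For gene lists, camera of limma 3.58.1 compared the members with all other genes at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 43 lists with at least 5 tested genes. The same test with the correlation estimated for each list, and fry, were run beside it. In fry, the directional p asks whether the members move, on balance, 1 way, and the mixed p whether they change in either direction, and neither compares the list with other genes. The mixed test passed for 20 lists in TMAO, 9 in GDCA against S, 4 in GDCA against SD, 1 in IAA against S and 0 in the remaining comparisons. The 45 lists fixed in advance covered cells and regions (astrocytes, reactive astrocytes, microglia, activated microglia, mature oligodendrocytes, oligodendrocyte precursors, excitatory and inhibitory neurons, endothelial barrier, pericytes and smooth muscle, meningeal fibroblasts, ependyma, choroid plexus, striatum, cerebellum, olfactory bulb, hypothalamus, thalamus), material that a dissection can carry along (red blood cells, peripheral immune cells, pituitary) and processes (immediate-early, glucocorticoid, circadian clock, heat shock, unfolded protein, NRF2, interferon, NF-kB and cytokine, senescence, histocompatibility with complement and ageing, cholesterol synthesis, bile acid handling, aryl hydrocarbon, tryptophan and serotonin, dopamine and noradrenaline, methylamine and osmolyte, insulin and feeding, synaptic vesicle, postsynaptic receptor, neurogenesis and proliferation, mitochondrially encoded, nuclear respiratory chain, ribosomal protein, sex-linked). The peripheral immune list of 17 genes and the pituitary list of 10 had fewer than 5 expressed members and were not tested.

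The genes named follow a rule: per comparison, up to 10 higher and 10 lower genes with the smallest p among those past the test, with a symbol and a mean of at least 10 counts, taking first those past against both S and SD. Where fewer than 10 passed, the 5 higher and 5 lower genes with the smallest p were added and are named as not passing. Up to 4 members of each list past camera, and up to 3 passing members of any other list, complete the rule, and the text gives a selection of them. Some genes that the rule takes are not reported here. The groups, comparisons, tests, lists, this rule and the first set of alternative settings were fixed before the data were examined.

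Replicate numbers recur in every group, so deviations from the group mean were correlated between libraries of the same number over 10811 genes. The correlations were 0.29 to 0.74 for GDCA with S, 0.36 to 0.63 for GDCA with SD, 0.17 to 0.79 for IAA with S, 0.16 to 0.74 for PA with S, 0.56 to 0.74 for PA with SD, 0.13 to 0.69 for SD with S, and 0.41 to 0.76 for GDCA with PA. In these comparisons the numbers were taken to pair the libraries, from the data and not from the labels. A library correlated best with its own number in 5 of 8 cases, apart from 7 for IAA with S and 6 for PA with SD. Replicates 1 and 2 also differed from 3 and 4 by GC content of the genes. That split could raise these correlations too, so matched mice were not shown. The fit with the number as a block is given where it changed a call or moved a count by more than 1.5 times. In IAA with SD, GDCA with IAA, IAA with PA and in Expt1 at least 1 pair did not correlate. In the first 3 it was number 3 (-0.34, 0.03 and -0.28). IAA replicate 3 followed GC content as replicates 1 and 2 did (Spearman's rho = -0.64).

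This first set held the replicate block, DESeq2 1.42.0, DESeq2 size factors, limma-voom with sample quality weights, no filter on low counts, 1 surrogate variable from sva 3.50.0, counts scaled from TPM by gene length, only the compared groups in the fit, S and SD pooled as 1 control, the second table, fry, an estimated correlation for lists, and the omission of each library in turn. Settings added after the data were seen were a GC correction (a smooth trend of log2 CPM against GC content per library as an offset, with a prior count of 2), that correction with the block or without TMAO replicate 3, a batch term for replicates 1 and 2 against 3 and 4, each of these pairs of replicates alone, Expt2 without replicate 4 of every group, the unnamed transcripts as features of their own, the omission of each library for the lists, and the comparisons of metabolites with each other.

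The tests were checked on simulated counts with the real means and library sizes. For TMAO against S (16028 genes) 60.6% of genes changed 1.5-fold and 72.2% of those changed 2-fold were recovered with 11 false calls, and for GDCA against S (16261 genes) 46% and 70.4% with 3 false calls. The simulated shift of 1 list was called in both, with 0 other lists. Genes were simulated independently of each other, so this step could not show how correlation between genes affects the list calls. The counts behind the recovery shares held no GC trend and no odd library, so recovery in the real libraries can differ. On counts simulated with a GC trend, the correction lowered false calls from 115 to 12 in the first design (16035 genes) and from 75 to 5 in the second (16259 genes).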

Results

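Messenger RNA was measured by sequencing in the left brain hemispheres of 28 C57BL/6 mice, 1 library per mouse, in 2 separate experiments. Each of the 7 groups held 4 mice. Expt1 had 2 groups, labelled S and TMAO, and Expt2 had 5 groups, labelled S, SD, GDCA, IAA and PA. TMAO is the usual abbreviation of trimethylamine N-oxide, formed from products of gut bacteria, and GDCA that of glycodeoxycholic acid, a bile acid. The labels spell out none of the abbreviations and do not say which of S and SD served as the vehicle for which metabolite, so each Expt2 metabolite was compared with both. In megacounts (M), the total estimated count per library lay between 21.53 and 31.95 M in Expt1 S and 23.52 and 26.44 M in TMAO. In Expt2 it lay between 18.29 and 25.91 M in GDCA, 17.09 and 21.24 M in IAA, and 17.87 and 20.96 M in PA. The vehicle groups of Expt2 had 18 and 22.71 M in S and 18.65 and 24.74 M in SD. Levels below are CPM, counts scaled to the library size, as mean ± SD of 4 mice. SE is an approximate standard error of a log2 change, its size divided by the square root of its F statistic. It is given for some of the genes past the test.

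The Expt1 comparison asked whether the brain transcriptome differed between mice given TMAO and those given vehicle. Per1, a clock gene that stimuli also induce acutely, was higher in TMAO, at 127 ± 8.13 against 81.1 ± 10.4 CPM (n = 4), a log2 change of 0.64 (SE 0.08). Jun, a subunit of the AP-1 transcription factor, rose from 43.1 ± 2.6 to 61.1 ± 4.45 CPM, a log2 change of 0.50 (SE 0.07). Arl4d, a small GTPase of the ARF-like family, rose from 11.9 ± 1.78 to 22.95 ± 3.77 CPM, a log2 change of 0.94 (SE 0.14). Each of these 3 genes was above every S mouse in all 4 TMAO mice. They were the 3 genes past the test among 16224 (edgeR quasi-likelihood, adjusted p = 0.0476 for each), and 2203 genes had an unadjusted p under 0.05. Leaving out TMAO replicate 3 gave 1629 genes, 622 higher and 1007 lower, S replicate 1 33 and S replicate 2 1, while leaving out S replicate 3, S replicate 4, TMAO replicate 2 or TMAO replicate 4 left 0 by the same tool. With every library included, DESeq2 called 143 genes (103 higher, 40 lower), limma-voom 1764 (842 higher, 922 lower), and counts scaled by gene length 0. Across 12100 genes, which are not independent replicates, the TMAO minus S difference followed GC content (Spearman's rho = 0.60), and correcting for GC content gave 23 genes.

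Most members of several fixed lists were higher in TMAO, and few of them passed one by one. Of the 25 immediate-early genes, which cells switch on within minutes of a stimulus, 24 were positive, with a median log2 change of 0.61, and 1 passed over all genes against 19 higher adjusted over the list alone. Egr1, a transcription factor of neuronal activity, stood at 278 ± 43.6 against 173 ± 21.5 CPM (adjusted p = 0.101), and Dusp1, a phosphatase that shuts down MAP kinases, at 44.1 ± 8.12 against 24.15 ± 5.6 CPM (adjusted p = 0.129). The list's camera adjusted p = 1.36e-30 with the preset correlation and adjusted p = 0.201 with an estimated correlation. Glucocorticoid-response genes were higher as a list, among them Tsc22d3, which encodes the anti-inflammatory protein GILZ, at 132 ± 4.12 against 93.1 ± 11.9 CPM (adjusted p = 0.0802). That list had camera adjusted p = 2.19e-09 and adjusted p = 0.233 with an estimated correlation, with 10 members higher and 2 lower adjusted over the list alone. Circadian clock genes (14 of 17 positive, 11 higher adjusted over the list alone), unfolded-protein stress genes (17 of 21 positive, 10 higher), cholesterol synthesis genes (21 of 22 positive, 9 higher) and striatal genes (13 of 15 positive, 9 higher) also passed camera upward. These 4 lists had adjusted p = 0.133, 0.159, 0.201 and 0.233 with an estimated correlation, and adjusted p = 0.0266, 0.0498, 0.0498 and 0.0498 with fry, which the immediate-early and glucocorticoid-response lists did not pass (0.0764 each). The clock gene Per2 had a log2 change of 0.47, the endoplasmic reticulum chaperone Calr 0.39, and the cholesterol enzyme gene Cyp51 0.21, all short of the test.

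**Figure D1:**
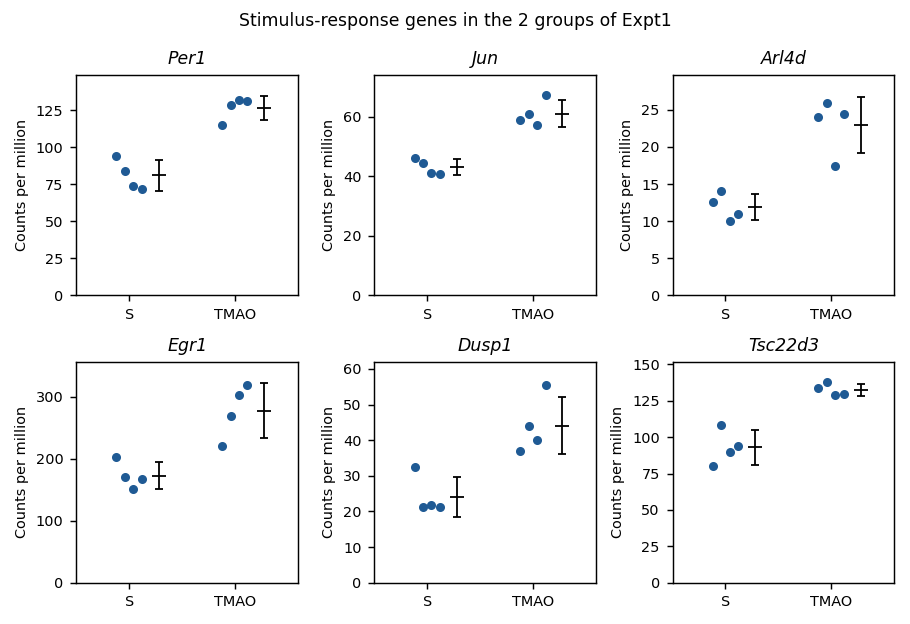
CPM of Per1, Jun, Arl4d, Egr1, Dusp1 and Tsc22d3 in the 2 groups of Expt1, with 1 point per mouse and a bar at the mean ± SD of 4 mice on a linear axis from 0. Every TMAO mouse lay above every S mouse for Per1, Jun and Arl4d, and Egr1, Dusp1 and Tsc22d3 did not pass the adjusted test.

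Another 10 lists passed camera in TMAO and had adjusted p = 0.313 to 0.513 with an estimated correlation. Heat shock genes (8 higher adjusted over the list alone), excitatory neuron genes (0), synaptic vesicle genes (0), mature oligodendrocyte genes (0), astrocyte genes (0), senescence genes (1 higher) and red blood cell genes (0) were higher. The 13 genes of the mitochondrial genome were all negative, with a median log2 change of -0.23 and 1 lower adjusted over the list alone, and mitochondrial genes held 6.47 ± 0.52% of the counts in TMAO against 7.25 ± 0.93% in S. Sex-linked genes (1 lower adjusted over the list alone) and cerebellar genes (1 lower) were also lower. The GC correction ended the camera calls of mitochondrially encoded (adjusted p = 0.490, now upward), sex-linked (0.230) and senescence genes (0.113), and with the block besides it ended that of cerebellar genes (0.0628). The single genes nearest the test in the negative direction were Tfrc, the transferrin receptor, at 92.2 ± 11.9 against 143 ± 18.9 CPM, Ddx3x at 248 ± 17.2 against 317 ± 18.1 CPM, and Xkr4 at 30.3 ± 1.45 against 40.3 ± 1.1 CPM, each with adjusted p = 0.0921. Cryab, a small heat shock protein, had a log2 change of 0.47 (adjusted p = 0.0872).

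Whether GDCA changed the brain transcriptome was asked first against S. Apold1, an early-response gene of endothelial cells, was at 2.92 ± 0.61 CPM in GDCA and 38.8 ± 9.63 CPM in S, 13.3-fold lower (log2 change -3.73, SE 0.28, n = 4). Ccn1, a secreted matrix protein that growth signals induce rapidly, was at 4.02 ± 1.06 against 32.9 ± 2.13 CPM, 8.16-fold lower (log2 change -3.03, SE 0.23). The secreted metalloproteinase Adamts1 was at 16.15 ± 1.39 against 44.6 ± 7.91 CPM (log2 change -1.47, SE 0.12). The vascular transcription factor genes Klf4 and Klf2 fell 3.22-fold and 3.25-fold, to 9.9 ± 2.87 and 9.44 ± 3.02 CPM. Nfkbia, the inhibitor of NF-kB, was at 13.2 ± 2.28 against 27.8 ± 2.67 CPM, and Zfp36, which destabilises inflammatory transcripts, at 3.15 ± 0.29 against 10.9 ± 1.13 CPM. The stress transcription factor genes Maff and Atf3 and the urokinase receptor gene Plaur were lower by log2 changes of -2.40, -2.77 and -3.23.

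In all, 51 of 16421 genes passed the test, 6 higher and 45 lower (smallest adjusted p = 3.42e-07, edgeR quasi-likelihood), and 946 had an unadjusted p under 0.05. The genes that rose were Mylip, a ubiquitin ligase, at 15.7 ± 1.3 against 10.3 ± 0.64 CPM, P4ha1, a collagen prolyl hydroxylase, at 48.6 ± 5.73 against 36 ± 1.64 CPM. The others were Apcdd1, an inhibitor of Wnt signals (log2 change 0.52), Rab11fip1 (0.81), the transcription factor gene Mycn (0.72) and a gene model named Chtf8 (4.32). The last overlaps another gene and lay at 1.65 ± 1.12 against 0.07 ± 0.06 CPM, so its counts are uncertain. With the replicate number as a block, 153 genes passed, 67 higher and 86 lower, of which 49 were shared. The GC correction gave 76, 19 higher and 57 lower, and the block with the GC correction 298, 170 higher and 128 lower. The count was 32 without GDCA replicate 2, 31 without GDCA replicate 3 and 30 without S replicate 4.

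Glucocorticoid-response genes were the list that moved most in GDCA: all 21 members were negative, 5 passed over all genes and 9 were lower adjusted over the list alone, with a median log2 change of -0.37. Sgk1, a kinase induced by glucocorticoids, was at 87.4 ± 24.1 against 198 ± 18.6 CPM, Ddit4, an inhibitor of mTOR, at 38.5 ± 5.24 against 71.4 ± 6.46 CPM, and Arrdc2 at 14 ± 0.91 against 28.6 ± 3.97 CPM. The list's camera adjusted p = 3.47e-29 held with an estimated correlation (adjusted p = 0.0326) and with fry (adjusted p = 0.0120). NF-kB and cytokine genes (11 members tested) had camera adjusted p = 0.00785, adjusted p = 0.0519 with an estimated correlation and fry adjusted p = 0.0120, with 2 lower adjusted over the list alone. Senescence genes, which include Plaur and the cell-cycle inhibitor Cdkn1a (29.5 ± 2.85 against 51.1 ± 6.47 CPM), had camera adjusted p = 5.21e-06, adjusted p = 0.0519 with an estimated correlation and fry adjusted p = 0.0200, with 2 lower adjusted over the list alone. The NF-kB and senescence lists had median log2 changes of -0.117 and -0.115. Nfkbia belongs to both the NF-kB and the glucocorticoid-response list, and Cdkn1a to both the senescence and the glucocorticoid-response list. These lists are thus not separate results.

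Single members of other lists passed as well in GDCA against S. Slc2a1, the glucose transporter of the blood-brain barrier, was at 135 ± 15.7 against 226 ± 29.2 CPM (adjusted p = 0.0386), while no other endothelial barrier gene passed over all genes and 2 were higher and 1 lower adjusted over the list alone. Nes, an intermediate filament of progenitor and vessel cells, Emp1, a membrane protein of the reactive astrocyte list, and Txnip, an inhibitor of thioredoxin, were lower by log2 changes of -1.04, -1.10 and -0.63. Among the immediate-early genes 4 passed downward, Ccn1, Klf4, Btg2 (log2 change -1.17) and Dusp1, which stood at 29.1 ± 10.6 against 60.9 ± 1.64 CPM with adjusted p = 0.0177, and adjusted p = 0.0585 with the replicate block. The immediate-early list itself went both ways, with 16 members positive and 9 negative, a median log2 change of 0.12, a mean of -0.18, and 1 higher and 4 lower adjusted over the list alone. Its camera adjusted p = 0.00811 downward became adjusted p = 0.856 with an estimated correlation and 0.2 with the block. With the block, its members Egr3 (log2 change 0.285, adjusted p = 0.0221), Bdnf (0.378, 0.0366) and Homer1 (0.378, 0.0398) came to pass upward. Ccn1, Klf4 and Btg2 still passed downward there. Heat shock genes were higher (camera adjusted p = 0.00167, 1 higher adjusted over the list alone), led by Hsph1 (log2 change 0.26, adjusted p = 0.169, blocked adjusted p = 0.0210). Genes of mature oligodendrocytes, reactive astrocytes, cholesterol synthesis, the NRF2 oxidative response and the ribosome were lower. These last 6 lists had adjusted p = 0.119 to 0.856 with an estimated correlation, and, apart from heat shock genes, reactive astrocyte genes (1 lower) and NRF2 genes (1 lower), none had a member past the test adjusted over the list alone.

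**Figure D2:**
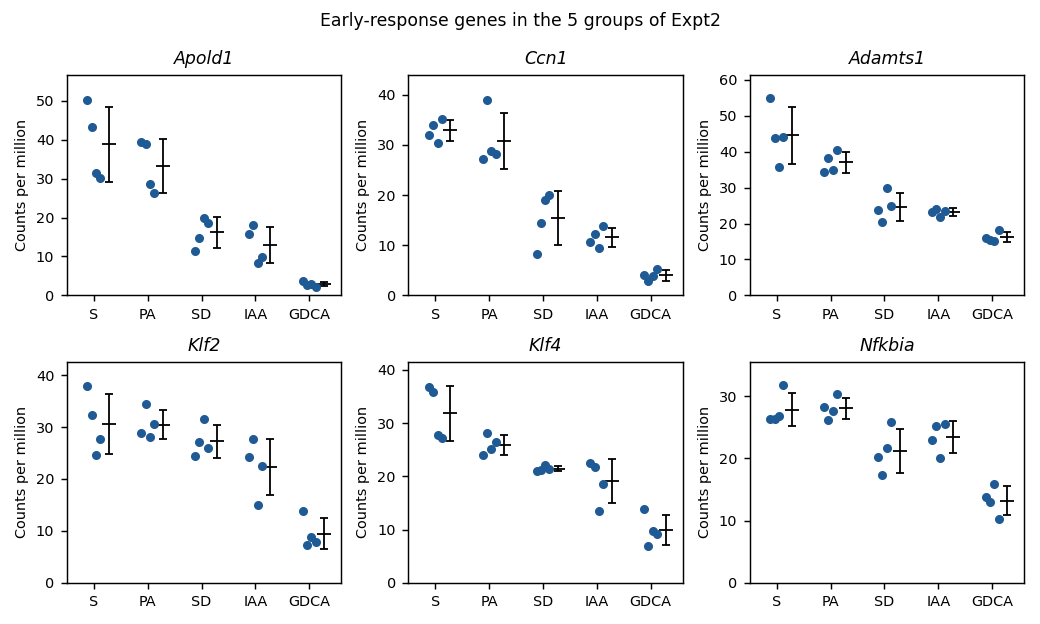
CPM of Apold1, Ccn1, Adamts1, Klf2, Klf4 and Nfkbia in the 5 groups of Expt2, in the order S, PA, SD, IAA and GDCA, with 1 point per mouse and a bar at the mean ± SD of 4 mice on a linear axis from 0. The GDCA mean was the lowest for each gene, and for Apold1 the group means were 38.8 in S, 33.2 in PA, 16.2 in SD, 12.95 in IAA and 2.92 in GDCA.

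Against SD, 4 genes passed in GDCA, all lower. Apold1 was at 2.92 ± 0.61 against 16.2 ± 3.89 CPM (log2 change -2.47, SE 0.28, adjusted p = 6.08e-04), Ccn1 at 4.02 ± 1.06 against 15.4 ± 5.33 CPM (log2 change -1.94, SE 0.23), Klf2 at 9.44 ± 3.02 against 27.2 ± 3.11 CPM (log2 change -1.53) and Klf4 at 9.9 ± 2.87 against 21.5 ± 0.52 CPM (log2 change -1.12, adjusted p = 0.00686). These 4 genes were also called lower against S. By edgeR's quasi-likelihood test 531 genes had an unadjusted p under 0.05. The replicate block gave 17 genes, 3 higher and 14 lower, 4 of them shared. It brought Zfp36 from adjusted p = 0.0632 to 0.00467, Nfkbia from 0.0723 to 0.0145, and Arrdc2 from 0.0737 to 0.0165, as well as P4ha1 from 0.289 to 0.0372 and Insig1 from 0.412 to 0.0460. Egr3 came to pass upward with the block (log2 change 0.374, adjusted p = 0.00854). The count was 7 without SD replicate 1, 8 without SD replicate 2, and 0 without replicate 4 of every group or with limma-voom.

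Cholesterol synthesis genes were lower in GDCA than in SD, with 21 of 22 members negative, a median log2 change of -0.13 and 2 lower adjusted over the list alone. Camera gave adjusted p = 1.03e-10, which held with an estimated correlation (adjusted p = 0.00197) and with fry (adjusted p = 0.00226). Insig1, a regulator of the sterol response, had a log2 change of -0.29. Heat shock genes were higher, with all 17 members positive and 2 higher adjusted over the list alone (camera adjusted p = 7.46e-09, adjusted p = 0.0160 with an estimated correlation, fry adjusted p = 0.0308). The inducible chaperone gene Hspa1b had a log2 change of 0.96 that did not pass alone. Unfolded-protein stress genes (6 higher and 2 lower adjusted over the list alone, with Hspa5 at 0.54 and Sdf2l1 at 0.74 on the log2 scale), all 16 cerebellar genes, red blood cell genes, microglial genes and mitochondrially encoded genes were also higher by camera. Glucocorticoid-response genes (17 of 21 negative, 4 lower adjusted over the list alone), mature oligodendrocyte genes (18 of 19 negative), senescence genes (1 lower) and immediate-early genes (16 of 25 negative, 1 higher and 4 lower) were lower. Members of the other lists in these 2 sentences did not pass adjusted over the list alone, and all 9 lists had adjusted p = 0.133 to 0.777 with an estimated correlation.

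The effect of IAA was likewise asked against each vehicle label. Against S, 9 genes passed, all lower. Adamts1 was at 23.2 ± 1.05 against 44.6 ± 7.91 CPM (log2 change -0.94, SE 0.12, adjusted p = 0.00147), Ccn1 at 11.6 ± 1.98 against 32.9 ± 2.13 CPM (log2 change -1.51, SE 0.21) and Apold1 at 12.95 ± 4.71 against 38.8 ± 9.63 CPM (log2 change -1.59, SE 0.24). Maff (-1.56), Plaur (-1.88), Ctla2a (-1.34), the transcription factor gene Foxf1 (-1.72), and Lrrc32 (-1.13) and Nrros (-0.63), which encode related proteins that bind latent TGF-beta, were also lower. Of these 9 genes, 9 were also called lower in GDCA than in S. By edgeR's quasi-likelihood test 642 genes had an unadjusted p under 0.05, and 32 passed with the replicate block, 12 higher and 20 lower, 9 of them shared. The count was 4 without IAA replicate 1 or IAA replicate 2, 3 without IAA replicate 3, IAA replicate 4, S replicate 1 or S replicate 4, and 2 without S replicate 2, and with S and SD pooled as 1 control it was 0.

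By camera, IAA against S had 9 lists past the test, and each had adjusted p = 0.502 to 0.960 with an estimated correlation. Interferon-response genes were higher, with 17 of 23 positive and 0 past the test adjusted over the list alone (camera adjusted p = 0.0219, and 0.0678 with the block). Ifit3b, an interferon-induced protein, had a log2 change of 0.49 that did not pass. Senescence genes (1 lower adjusted over the list alone, Plaur), unfolded-protein stress genes (1 lower, and camera adjusted p = 0.0618 with the block), glucocorticoid-response genes (19 of 21 negative, 0 past), reactive astrocyte genes (0), microglial genes (0), activated microglia genes (0), red blood cell genes (0, and 0.0856 with the block) and ribosomal protein genes (0) were lower. The GC correction ended the camera calls of activated microglia (adjusted p = 0.0629), unfolded-protein stress (0.0799) and ribosomal protein genes (0.123). It brought in mitochondrially encoded (0.00377), mature oligodendrocyte (0.0402) and cerebellar genes (0.0488), all lower. Synaptic vesicle genes, with camera adjusted p = 0.0838, had 0.0117 with the block. The estimated correlation was run with neither the GC correction nor the block, and in the fit without them it left 0 lists past the test. The genes nearest the test upward were Rbm15, an RNA-binding protein gene (log2 change 0.39, adjusted p = 0.321), and Zswim3 (0.52, adjusted p = 0.504).

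Against SD, interferon-response genes were again higher in IAA, with 17 of 23 positive (camera adjusted p = 0.00212, adjusted p = 0.567 with an estimated correlation). Ifit1 had a log2 change of 0.83 and Ifit3b of 0.52. Mitochondrially encoded genes (13 of 13 positive) and unfolded-protein stress genes (17 of 21 positive) were higher and striatal genes (12 of 15 negative) lower by camera. The GC correction moved mitochondrially encoded genes to adjusted p = 0.444 and striatal genes to 0.0661. Each of these 3 lists had adjusted p = 0.977 with an estimated correlation, and 0 members of the 4 lists passed adjusted over the list alone. No gene passed one by one. edgeR's quasi-likelihood test, DESeq2 and limma-voom called 0 genes each, 322 had an unadjusted p under 0.05, and leaving out IAA replicate 1 gave 1 gene.

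For PA, cholesterol synthesis genes were higher than in S, with 19 of 22 positive, a median log2 change of 0.10 and 0 past the test adjusted over the list alone. Camera gave adjusted p = 8.57e-06, which held with an estimated correlation (adjusted p = 0.0418), and fry gave adjusted p = 0.0984. Insig1 was at 94.9 ± 5.25 CPM in PA (log2 change 0.21) and did not pass the test alone. Immediate-early genes (22 of 25 positive, with Egr1 at a log2 change of 0.48) were higher. Red blood cell, cerebellar, reactive astrocyte, pericyte and smooth muscle, senescence, olfactory bulb and microglial genes were lower. These 8 lists had adjusted p = 0.452 to 0.621 with an estimated correlation and 0 members past the test adjusted over the list alone. Gene by gene, edgeR's quasi-likelihood test, DESeq2 and limma-voom called 0 genes each in PA against S, and 336 had an unadjusted p under 0.05.

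Against SD, the genes of PA nearest the test were Adamts1 (37 ± 2.95 against 24.7 ± 3.89 CPM, log2 change 0.58) and Ccn1 (30.8 ± 5.49 against 15.4 ± 5.33 CPM, 0.99), both with adjusted p = 0.977, and Apold1 (1.04). By edgeR's quasi-likelihood test 0 genes passed and 275 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 2. Unfolded-protein stress genes (21 of 21 positive, 1 higher adjusted over the list alone), glucocorticoid-response genes (18 of 21 positive, 0), immediate-early genes (21 of 25 positive, 1), heat shock genes (0), NRF2 genes (0), mitochondrially encoded genes (0), insulin and feeding genes (1, the melanocortin receptor Mc4r) and NF-kB and cytokine genes (1, and camera adjusted p = 0.0510 with the block) were higher by camera, with adjusted p = 0.166 to 0.923 with an estimated correlation. Endothelial barrier genes had camera adjusted p = 0.158 downward, and 0.0346 with the block. The estimated correlation was not run with the block, and without it left 0 lists past the test in PA against SD.

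The vehicle labels of Expt2 were compared with each other. Adamts1 was lower in SD, at 24.7 ± 3.89 against 44.6 ± 7.91 CPM in S (log2 change -0.85, SE 0.12, n = 4, edgeR quasi-likelihood adjusted p = 0.00621). It was the single gene past the test, and 566 had an unadjusted p under 0.05. With the replicate block 10 genes passed, among them Ccn1 (unblocked adjusted p = 0.178, blocked 0.0488), Ccn2, another secreted matrix protein of its family (0.178, blocked 0.0229), Maff (0.204, blocked 4.51e-04) and Plaur (0.224, blocked 0.0169). The count was 0 without SD replicate 1 or SD replicate 2, 2 without S replicate 2 and 3 without SD replicate 4, and 0 when only SD and S were fitted. Glucocorticoid-response genes (19 of 21 negative), unfolded-protein stress genes (19 of 21 negative, 1 lower adjusted over the list alone), reactive astrocyte genes (1 lower), senescence genes (1 lower), NF-kB and cytokine genes (0), microglial genes (0), all 16 cerebellar genes, all 13 mitochondrially encoded genes (median log2 change -0.25), red blood cell genes (median -0.96), NRF2 genes and ribosomal protein genes were lower in SD by camera, and cholesterol synthesis genes higher. These 12 lists had adjusted p = 0.134 to 0.858 with an estimated correlation. SD replicate 3 stood apart in mitochondrial counts, with 2.32% against 4.04% to 5.61% in the 3 other SD mice, and it enters each comparison with SD. The list of histocompatibility, complement and ageing genes had camera adjusted p = 0.0650, and 0.0245 with the block.

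The single test of any difference among the 5 groups of Expt2 called 28 of 16421 genes, led by Ccn1, Adamts1 and Apold1 (adjusted p = 2.9e-06 each) and followed by Klf4, Zfp36, Atf3, Nfkbia, Klf2, Maff and Plaur. It gave 456 genes with an unadjusted p under 0.05, and 74 genes with the replicate block. The S groups of the 2 experiments differed in 6086 of 16874 genes, 2546 higher and 3540 lower in Expt1 (edgeR quasi-likelihood, 7889 with an unadjusted p under 0.05), in 3957 without Expt2 S replicate 4, in 1981 with the GC correction and in 2262 with 1 surrogate variable. Metabolites were compared within their own experiment only, a choice fixed before this difference was seen.

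Of the 43 lists tested, 17 passed camera in no comparison in the fit by group alone, without a block or GC correction. The smallest adjusted p of each of these lists across the 8 comparisons was between 0.0650 and 0.711. They covered bile acid handling (smallest adjusted p = 0.570), methylamine and osmolyte genes (0.711), tryptophan and serotonin (0.185), the aryl hydrocarbon response (0.394), dopamine and noradrenaline (0.111), histocompatibility, complement and ageing genes, nuclear respiratory chain genes (0.299), postsynaptic receptors (0.579), neurogenesis and proliferation (0.0999), endothelial barrier genes, and markers of the choroid plexus, ependyma, hypothalamus, thalamus, inhibitory neurons, oligodendrocyte precursors and meningeal fibroblasts. The bile acid and methylamine lists are those nearest to GDCA and TMAO by name, with 10 of 25 and 12 of 16 members expressed enough to be tested. With the block, endothelial barrier genes passed camera in PA against SD (adjusted p = 0.0346). Histocompatibility, complement and ageing genes did so in SD against S (adjusted p = 0.0245). fry gave 4 lists in TMAO, 3 in GDCA against S, 2 in GDCA against SD and 0 in the other 5 comparisons.

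**Figure D3:**
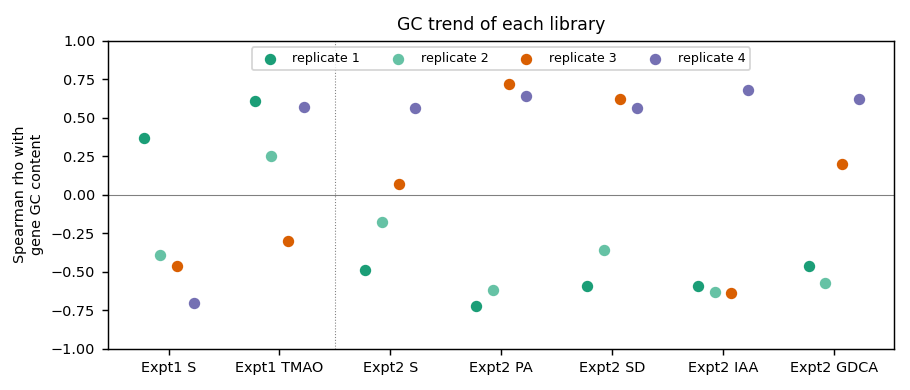
Spearman correlation, across genes, of each library's deviation from its experiment's mean expression with gene GC content, for the 7 groups, coloured by replicate number. In Expt2 replicates 1 and 2 lay below 0 in every group and replicates 3 and 4 above it except IAA replicate 3 (-0.64), and in Expt1 S replicate 1 and TMAO replicates 1, 2 and 4 lay above 0.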

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

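The GC tests, the handling test, the time-of-day test and the splits for genes and lists of GDCA against S were chosen only after the result was seen, while the vessel-cell test, the tissue-mix test and the other splits were chosen before.

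Single libraries stood far from the 3 others of their group in 5 of 71 groups looked at, and chance gives about 1 in 20. IAA replicate 3 had a total of 21.24 M counts against 17.09 to 17.41 M. Expt2 S replicate 1 had 5.58% of counts from mitochondrial genes against 4.51% to 4.66%. Ccn1 was at 38.95 CPM in PA replicate 2 against 27.13 to 28.76, Nfkbia at 31.8 CPM in Expt2 S replicate 4 against 26.34 to 26.75, and Dusp1 at 32.54 CPM in Expt1 S replicate 1 against 21.16 to 21.7. Over all named genes the number was 107 of 1620 groups, with 18 in IAA replicate 4, 14 in Expt2 S replicate 4 and at most 7 in any other library. Expt2 S replicate 4, which enters each comparison with that group, was also the farthest library of Expt2 on the first principal component (40.3, with 28.8 the next). Among 1320 tested transcripts without a gene name, 3 were called in GDCA against S.

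The 45 genes called lower in GDCA than in S, among them Apold1, Ccn1, Klf4 and Slc2a1, were weighed first. GC content was not the whole cause, because 45 of the 45 genes stayed called with the block and the GC correction and their median log2 change moved from -1.10 to -1.08. The endothelial list argued against a smaller share of blood vessel cells as the whole cause, with a median log2 change of -0.003 (20 genes, SD 0.29). Its members included Cldn5 at 0.55, Slco1a4 at 0.25, Flt1 at 0, Pecam1 at -0.09 and Mfsd2a at -0.28. The lowest was Slc2a1 at -0.74, itself among the 45 genes. Handling or collection of the animals may account for part of it, since the 23 genes lower in GDCA than in PA had a median log2 change of -0.55 in SD against S, where 22 of 23 were lower, though other splits of the 8 libraries gave medians of up to 0.45 in size against 0.52 for the real one on mean log2 CPM. A difference between the vehicles would give that value too, and an effect of GDCA itself, untested against either, stays open. The 23 genes were also all lower in Expt1 S than in Expt2 S, with a median log2 change of -1.29. They thus varied under 1 vehicle label as well, though between experiments that differed in many other genes.

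The immediate-early genes higher in TMAO than in S, such as Jun and Egr1, were weighed next. GC content was not the whole cause, because after the GC correction the median log2 change of the list was 0.53 (SD 0.33, 25 of 25 positive) against 0.61 before. The time of day of collection could also raise such genes. It cannot be told apart from the group, since the difference between clock genes of opposite phase was 0.11. The median was 0.17 for 8 genes of the phase of Per3 and Dbp, which ranged from -0.11 (Per3) to 0.62 (Ciart). For 3 genes of the phase of Arntl it was 0.05, with a range from -0.2 (Clock) to 0.08 (Arntl). The difference was too small to point to a shift in phase, and the genes were too few to rule it out. An effect of TMAO stays open and was not tested separately.

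In Expt2, replicates 1 and 2 stood apart from replicates 3 and 4, with 7071 of 16421 genes called between them. The difference followed GC content (Spearman's rho = 0.76 across genes, with IAA replicate 3 on the side of replicates 1 and 2), and after the GC correction 3774 genes were still called, so how far GC content alone accounts for it cannot be told apart from other differences between these libraries. Another mix of brain regions or cell types is a candidate explanation, as the choroid plexus list still differed by a median log2 of 0.33 after the correction, the most of 16 lists, with the hypothalamus list at 0.26 and the meningeal fibroblast list at 0.22. The design gives no biological difference between replicate numbers, and none was tested.

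Each comparison was set against the other splits of its 8 libraries into 4 and 4, of which there are 35 with the real one. For GDCA against S (51 genes, highest other 0), GDCA against SD (4, highest other 2), IAA against S (9, highest other 1), SD against S (1, highest other 0), S of Expt1 against S of Expt2 (6086, highest other 0) and GDCA against IAA (6, highest other 0), 1 of the 35 splits, the real one, gave as many genes. For the S groups chance was excluded by this only if the numbers do not pair the libraries, which was not examined for them. In the first 4 the numbers were taken to pair the libraries, and in GDCA against IAA 3 of 4 pairs correlated. There only 8 splits part all pairs as the real one does, too few for a share under 0.05. The highest other among those 8 was 1 for GDCA against SD and 0 for the 4 others. For the joint test (28 genes, highest other 1) the real one alone of 100 splits, drawn without regard to number, gave as many. For TMAO against S (3 genes) 2 of the 35 splits gave as many, and chance was not excluded. The other one called 2993 genes, a structure of the samples: it set S replicate 1 and TMAO replicates 1, 2 and 4, the 4 libraries with a positive GC trend, against the rest. S replicate 1 (rho = 0.37) and TMAO replicate 3 (-0.30) thus resembled the other group in GC trend, and in the side of the first principal component of Expt1 (-5 and 20.7). TMAO replicate 3 stood apart from both groups on the second component (33.3, with 7.4 the next), and S replicate 1 on the third (33.5, with 3 the next). Library batches or an exchange of these 2 labels could not be settled. Per1 (94.4 and 132 CPM), Jun and Arl4d in these 2 libraries sat with their labelled groups, but those genes were picked by the labels. For GDCA against PA (24 genes) 2 of the 35 splits gave as many, the other being replicates 1 and 2 against 3 and 4 with 2351 genes, and the same division called 3516 genes in PA against SD, whereas the 8 splits that part all pairs as the real one does, too few for a share under 0.05, had a highest other of 0 in both. Chance was not excluded for IAA against PA (1 gene, 2 of 35, highest other 1). IAA against SD (highest other 2), PA against S (highest other 0) and PA against SD called 0 genes, so all 35 of 35 splits gave as many by construction and nothing was tested. For the number of lists past camera, chance was excluded in no comparison: TMAO against S had 16 lists and 4 of 35 splits as many (highest other 23), GDCA against S 10 and 24 (19), GDCA against SD 11 and 20 (23), IAA against S 9 and 10 (14), IAA against SD 4 and 30 (13), PA against S 9 and 8 (14), PA against SD 8 and 7 (11), and SD against S 12 and 5 (19).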

How the results depend on the processing

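The GC correction, the batch term, the pairs of replicates alone, Expt2 without replicate 4, the unnamed transcripts, the metabolite comparisons and the omission of libraries for lists were chosen after seeing the data. Numbers are genes past the test unless lists are named. Where a value moved the cause was not tested, except that fewer libraries were fitted when some were left out. Without a block 3 genes passed in TMAO against S, 51 in GDCA against S, 4 in GDCA against SD, 9 in IAA against S, 1 in SD against S, 24 in GDCA against PA, 6 in GDCA against IAA, 1 in IAA against PA, 28 in the joint test and 6086 between the S groups. The replicate block gave 5, 153, 17, 32, 10, 57 for the first 6, 2 for IAA against PA and 74 for the joint test. Where the numbers were taken to pair the libraries, it changed no list call other than those given with the results. For genes it changed calls beyond those given there. Adamts1 (adjusted p = 0.0256), Maff (0.0291) and Atf3 (0.0429) came to pass in GDCA against SD, and Zfp36 (0.00761), Klf4 (0.0312) and Ccn2 (0.0143) in IAA against S, while Arl4d no longer passed in GDCA against S. In TMAO against S, where 2 of 4 same-number pairs correlated and 2 of 8 libraries correlated best with their own number, numbers did not pair the libraries, nor in IAA against SD, GDCA against IAA and IAA against PA. In TMAO the 5 genes with the block were Per1, Arl4d, Tsc22d3 (adjusted p = 0.0347), Lcn2 and Ddit4, and Jun was not among them. Where numbers did not pair, the block moved the camera adjusted p of red blood cell genes to 0.0590 in TMAO, and of unfolded-protein stress genes to 0.119 and sex-linked genes to 0.0193 in IAA against SD. The block with the GC correction gave TMAO 12, GDCA against S 298 (170 higher, 128 lower, 51 shared), GDCA against SD 23, IAA against S 30, PA against S 1, PA against SD 1, SD against S 12, GDCA against PA 71, IAA against PA 6, the joint test 110, the S groups 2587, and 14 lists for IAA against S in place of 9. In the paired comparisons that fit ended the camera calls of immediate-early genes in GDCA against S (adjusted p = 0.509) and against SD (0.0930), of red blood cell genes in IAA (0.0664) and PA against S (0.0764) and of NF-kB and cytokine genes in PA against SD (0.0555). The GC correction alone gave TMAO 23, GDCA against SD 9, SD against S 3, GDCA against PA 40, IAA against PA 2 and the S groups 1981, and it moved ribosomal protein genes in SD against S to a camera adjusted p = 0.0513. Without TMAO replicate 3 that correction gave 1267 genes (587 higher, 680 lower), 739 of them shared with the 1629 called without that library. In that setting Calb1, a gene of Purkinje cells, turned from a log2 change of -0.105 to 0.15 (adjusted p = 0.0236), the 1 reversal past the test. One surrogate variable gave TMAO 32, GDCA against S 159 (57 higher, 102 lower), GDCA against SD 20, IAA against S 17, SD against S 10, GDCA against PA 57, IAA against PA 0, the joint test 66 and the S groups 2262. DESeq2 gave TMAO 143, GDCA against S 84 (22 higher, 62 lower), GDCA against SD 19, IAA against S 15, PA against SD 2, SD against S 9, GDCA against IAA 14, GDCA against PA 49, IAA against PA 3 and the joint test 68. limma-voom gave TMAO 1764 (842 higher, 922 lower), GDCA against SD 0, IAA against S 18, SD against S 3 and GDCA against IAA 1. Without a filter TMAO gave 40, GDCA against SD 9 and IAA against PA 0. Counts scaled by gene length gave TMAO 0, IAA against S 5 and GDCA against PA 15. The batch term for replicates 1 and 2 against 3 and 4 gave GDCA against S 91, GDCA against SD 12, IAA against S 16, SD against S 7, GDCA against PA 48, IAA against PA 3 and the joint test 52. Replicates 1 and 2 only gave GDCA against SD 7, IAA against SD 1, PA against S 3, PA against SD 10, SD against S 17, GDCA against PA 60, IAA against PA 2 and the joint test 65. Replicates 3 and 4 only gave GDCA against S 20, GDCA against SD 9, IAA against S 2, SD against S 0, GDCA against IAA 1, GDCA against PA 15 and the joint test 13. Only the 2 compared groups gave GDCA against S 32, GDCA against SD 2, IAA against S 3, SD against S 0 and GDCA against IAA 0. S and SD pooled gave GDCA 29 and IAA 0. Without replicate 4 of every group GDCA against S gave 29 and GDCA against SD 0. Unnamed transcripts as features gave TMAO 0, IAA against S 5 and IAA against PA 0. An estimated correlation left 0 of 16 lists in TMAO, 1 of 10 in GDCA against S, 2 of 11 in GDCA against SD, 0 of 9 in IAA against S, 0 of 4 in IAA against SD, 1 of 9 in PA against S, 0 of 8 in PA against SD and 0 of 12 in SD against S. In the same order fry left 4, 3, 2, 0, 0, 0, 0 and 0. Leaving out each library in turn gave 0 to 1629 in TMAO, 30 to 41 in GDCA against S, 4 to 8 in GDCA against SD, 2 to 6 in IAA against S, 0 to 1 in IAA against SD, 0 to 0 in PA against S and PA against SD, 0 to 3 in SD against S, 1 to 8 in GDCA against IAA (2 without GDCA replicate 2, 3 or 4, 1 without IAA replicate 2 or 4), 17 to 27 in GDCA against PA, 0 to 1 in IAA against PA (0 of them Ccn1, the gene called without IAA replicate 1 being another), and 3957 to 6231 between the S groups. For lists the ranges were 12 to 17 in TMAO, 5 to 18 in GDCA against S, 8 to 16 in GDCA against SD, 4 to 14 in IAA against S, 2 to 8 in IAA against SD, 6 to 11 in PA against S, 4 to 11 in PA against SD and 9 to 16 in SD against S. Apold1, Ccn1, Klf4 and Adamts1 passed in GDCA against S under all alternatives run, with Apold1 between -3.87 and -3.10. Per1, Jun and Arl4d were positive in TMAO under all alternatives, with an adjusted p of up to 0.443. Over all named genes and alternatives 8898 values stayed on their side of the test, 318 came to pass, 338 no longer passed and 1 reversed. DESeq2 size factors and the second table moved no count by more than 1.5 times. Depth limits genes near 0 CPM such as Chtf8 and Plaur, where few counts stand behind the fold.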

Other observations

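The comparisons of metabolites with each other, and the 23 genes followed across groups, were chosen only after the results were seen.

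Ccn1 was lower in GDCA than in PA by a log2 change of -2.93 and Apold1 by -3.51 (adjusted p = 1.18e-06), with Adamts1 at -1.20, and 24 genes passed, 1 of them, Apcdd1, higher (log2 change 0.52). Depp1, a gene induced by FOXO factors, and Tcim, a regulator of transcription, were 12.9-fold and 3.81-fold lower in GDCA than in PA. Their average levels in Expt2 were low, at a log2 CPM of 1.03 and 1.19, near that of Plaur (0.99), so few counts stand behind these folds. Under the alternative settings the log2 change of Depp1 lay between -4.65 and -2.66, past the test in 21 of 23. That of Tcim lay between -2.33 and -1.55, past the test in 22 of 23. Against IAA, 6 genes were lower in GDCA: Apold1 by a log2 change of -2.14 (adjusted p = 0.00605), Ccn1 by -1.52, Klf2 by -1.24, Klf4 by -0.95, Nfkbia by -0.82 and Arrdc2 by -0.92. The count was 2 without GDCA replicate 2, 3 or 4, 1 without IAA replicate 2 or 4, and 0 when only GDCA and IAA were fitted. Between IAA and PA 1 gene passed, Ccn1, lower in IAA by -1.42 (adjusted p = 0.0336), and no fit that left out 1 library kept this call. In that comparison 283 genes had an unadjusted p under 0.05. With the replicate block GDCA against PA gave 57 genes, 12 higher and 45 lower.

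The 23 genes lower in GDCA than in PA were followed in other comparisons, without a test of the set. All 23 were lower in IAA than in S, with a median log2 change of -0.71, and 16 of 23 were lower in IAA than in SD, with a median of -0.14. In Expt1 none of the 23 was lower in TMAO than in S, and the median was 0.59. Between the S groups all 23 were lower in Expt1, with a median of -1.29. Mean Klf2 was 30.6 CPM in Expt2 S, 30.5 in PA, 27.2 in SD, 22.3 in IAA and 9.44 in GDCA, and mean Klf4 was 31.8, 25.9, 21.5, 19.1 and 9.9 CPM in the same order.

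Comparisons that share libraries share chance values. GDCA against S and GDCA against SD shared 4 calls, where independent lists would share 0.011 and 20 simulations with unchanged groups at most 1. The correlation of their log2 changes over 16421 genes was 0.59 against 0.50 simulated, and the covariance 0.0478 against 0.0325. With the GDCA libraries divided between them, 5 calls were shared of 29 and 6, the correlation was 0.14 and the covariance 0.0248. GDCA against S and IAA against S shared 9 calls, where independent lists would share 0.0247 and the simulations shared 0. Their correlation was 0.62 against 0.50 simulated, with covariance 0.0516 against 0.0332. With the S libraries divided, 3 calls were shared of 19 and 4, the correlation was 0.13 and the covariance 0.0213. The simulations changed no group, and independent lists share no libraries. Neither overlap therefore shows how many calls a shared group brings once 1 group differs.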
